A study of Caenorhabditis elegans with 7 samples.

How the data were processed

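Labelled and total RNA of whole L4 larvae was measured in 7 libraries, 4 of a control strain without FLP recombinase and 3 of a strain with FLP in the hypodermis. Groups and replicate numbers were taken from the sample titles. Libraries were made with a 3′ mRNA sequencing kit after alkylation of RNA with iodoacetamide, per the labels' protocols. The per-library counts were made by the authors with slamdunk 0.4.3, per the file headers. These deposited counts give, for each of 47039 3′ UTR entries, the reads, the reads with at least 1 T>C mismatch, the covered T positions and the converted Ts. The deposited fraction, the conversion rate, equals converted Ts divided by covered Ts in each file. The deposited score is a CPM, the read count scaled to the mapped reads of the library. It served only to back-calculate the mapped reads of each library, since entries of isoforms overlap and share reads. The deposited table of the whole series gives a p-value, an adjusted p-value, the mean conversion fraction per strain and the ratio of these means for 198 genes, which the authors picked, per the file's name, with at least 17 T>C and a false discovery rate of 10%. Of that table's values per library, the converted Ts equal those of the library files, and 14 other columns were not used. The test behind the authors' p-value is not given in the sources used here. DESeq2 and the genome build ce10 are named in the submitters' processing notes, without a role for the tool. The annotation named in the file headers is of WBcel235, and of 19463 entries with an annotated 3′ UTR in WBcel235, 18998 (97.6%) had the same stop codon side, so coordinates are given for WBcel235. The trimming, the T>C threshold per read and any masking of variants are not given in the sources used here. The deposited column of multimapping counts is 0 in all entries, so reads shared by near-identical genes may have been placed in 1 of them or left out.

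Entries were joined to genes through their transcript name (42202 entries) or sequence name (4816 entries). The 21 entries without a gene held 0.00444% of reads and were left out of library sizes and tests. Where entries of a gene overlapped, only the entry with the most reads over all libraries was kept, so that no read counted more than once in a gene. This left 33967 entries in 27909 genes. It departs from the design, in which entries of the same name were to be summed, because the entries of isoforms repeat each other's reads. A total of 3411 genes share UTR sequence on the same strand with another gene and remain uncertain. None of the genes named with their values is among them. Gene-level reads ranged from 5040693 to 61924868 per library. Strand was not checked beyond the annotation's own.

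Labelling was tested on pairs of counts per gene and library, reads with T>C and reads without. The test was edgeR 4.0.16's quasi-likelihood F-test in R 4.3.3, two-sided, with a term per library, a term for labelled reads, and the tested term of labelled reads in the hypodermal group. Both counts of a library had the same library size and no further scaling. Genes entered with a mean of 20 or more reads per library and 10 or more T>C reads in total. Negative F values were set to 0. Total reads per gene were tested with edgeR's quasi-likelihood F-test after TMM scaling, over genes with a mean of 20 or more reads, and in DESeq2 1.42.0 as an alternative, where 63 genes had no adjusted p and were left out of its counts. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors are the log2 estimate divided by the root of F. CPM values use the TMM library sizes, except in the comparison of pgp-6 with its neighbours, which uses all gene reads. Library and list percentages were compared by exact permutation tests over all 35 splits (20 without control replicate 2), one-sided because the construct can only add label. A binomial interval is a Wilson interval at 95%. The interval of a ratio of pooled reads is exact and conditional on their total. Python 3.11.15, pandas 2.3.3, SciPy 1.17.1, NumPy 2.4.6 and matplotlib 3.10.9 were also used.

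The samples, tests, alternatives, rule for named genes and 16 gene lists were fixed before the data were examined. The lists are cuticle collagens, other hypodermal genes, seam cells, intestine, body wall muscle, pharynx, neurons, germline, sperm, coelomocyte with excretory and gonad sheath cells, glia, ribosomal proteins, adult stage, heat and ER stress, pyrimidine metabolism, and nuclear envelope and pore. Some lists share members, such as the yolk protein genes in the intestine and adult-stage lists. Lists were tested with limma 3.58.1, by cameraPR on the signed root of F for labelling and by camera on log2 CPM for reads, at a preset correlation of 0.01 and again with a correlation estimated from the libraries. For labelling the latter used log2 odds with 0.5 added to each count. The named genes were to be, for labelling, genes past the threshold with no overlap between groups (10 by odds ratio, 10 by difference, 5 lower), the 3 most-read members of each list, and dpy-7, lin-26, col-19, unc-54, myo-2, vit-6, elt-2, rab-3, glh-1 and pgl-1. For reads they were up to 8 higher and 8 lower genes past the threshold with no overlap. No gene met the first part of the rule, and the others gave 56 genes. Other genes in the text are said to be chosen after their values were seen, belong to a call described beside them, or come from the authors' deposited table.

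Alternatives for labelling were converted Ts of covered Ts, a quasi-binomial model, centring of libraries on the median gene, no read filter, a mean of 100 reads, leaving out genes above 20% in controls, each entry tested alone, the replicate number as a block, each replicate left out and a threshold of 0.1. For reads they were DESeq2's size factors in edgeR, DESeq2's Wald test, no filter, a mean of 100 reads, the block and each replicate left out. A beta-binomial test, limma on log2 odds, a batch term, the flow cell libraries alone, centring on pooled odds, leaving out control replicates 2 and 3 together, and a list's odds relative to all reads were added after seeing the data. The headers of 5 libraries name a flow cell and those of control replicate 1 and hypodermal replicate 1 do not, and this split served as the batch. Control replicates 2 and 3 were doubted for the highest share of T>C reads and the fewest genes with reads.

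The tests were tried on simulated data drawn from the real means and depths and the fitted dispersion trend with 200 changed genes. For labelling, all genes kept each library's real overall share of T>C reads, with control replicate 2 included. Counts followed edgeR's fitted dispersion, so the setting is not neutral between the tools. False calls are thus calls outside the 200 genes, not errors in genes free of any difference between libraries. For labelling over 9821 genes, edgeR recovered 0% of 80 genes changed 2-fold, 8.33% of 60 changed 4-fold and 13.3% of 60 changed 8-fold in odds, with 0 false calls. The quasi-binomial model recovered 0%, 5.0% and 5.0% with 1 false call, and the beta-binomial test 2.5%, 8.33% and 8.33% with 32 false calls, more than its true calls. For total reads over 12465 genes, edgeR recovered 6.25%, 46.7% and 78.3% of genes changed 2-, 4- and 8-fold, with 4 false calls. No pair of libraries was a copy of another (log2 CPM correlated across genes at 0.793 to 0.944 between libraries). The authors' upper and lower bounds of the conversion rate were not used here.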

Results

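Whole L4 larvae of Caenorhabditis elegans were profiled by SLAM-ITseq, a method that marks the transcripts made in a chosen tissue of an intact animal. In this method, cells that express uracil phosphoribosyltransferase build fed 4-thiouracil into new RNA, and after alkylation with iodoacetamide the thiouracil sites are read as T-to-C mismatches (T>C). Strain BN1190 carried FLP recombinase in the hypodermis, the epidermal tissue that secretes the cuticle, and strain BN1158 without FLP was the control. Larvae grew for 28 h at 20 °C on 3 plates per sample before 4-thiouracil was added for a total of 17 h. There were 4 control and 3 hypodermal libraries of mRNA 3′ ends. Reads counted in the 3′ UTRs of genes numbered 51976160, 5040693, 8537578 and 20058447 in control replicates 1 to 4 and 61924868, 20317812 and 18982439 in hypodermal replicates 1 to 3. Genes with at least 1 read numbered 11081 in control replicate 3 and between 12981 and 14230 in the other libraries. Per the labels each replicate had plates of its own, but not whether replicates were started from separate cultures or on separate days, so the p-values measure the spread between these samples, which may be partly technical. Intervals given for single libraries cover counting error only, since no molecular identifiers are named for these reads.

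The first question was whether libraries from animals with FLP in the hypodermis held more labelled reads than the control background. Reads with T>C made up 3.16% ± 0.952 (SD, n = 4) of gene reads in the control libraries and 3.56% ± 0.206 (SD, n = 3) in the hypodermal libraries. The difference of 0.40 percentage points was smaller than the spread between control libraries (one-sided exact permutation test, p = 0.314, where 35 splits allow a smallest p of 0.0286). Control replicate 2 held 4.58% labelled reads (95% Wilson interval 4.57 to 4.60), above the 3.35%, 3.57% and 3.76% of hypodermal replicates 1 to 3. The other controls held 2.64%, 2.79% and 2.63%. Without control replicate 2 the control mean was 2.69% ± 0.0868, each hypodermal library lay above each remaining control, and the difference was 0.874 points with an exact one-sided p of 0.05, the smallest that 20 splits allow. With control replicates 1, 3 and 4 left out in turn the difference was 0.226, 0.275 and 0.224 points. With hypodermal replicates 1 to 3 left out in turn it was 0.504, 0.397 and 0.298 points. Among the 5 libraries whose headers name a flow cell (control replicates 2 to 4, hypodermal replicates 2 and 3) the difference was 0.330 points, and between control replicate 1 and hypodermal replicate 1 it was 0.714 points. Converted Ts made up 0.142% ± 0.0593 of covered Ts in controls and 0.154% ± 0.0171 in hypodermal libraries (exact one-sided p = 0.4). The median tested gene had 1.45% ± 1.19 labelled reads in controls and 2.59% ± 0.286 in hypodermal libraries (exact one-sided p = 0.0857).

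**Figure D1:**
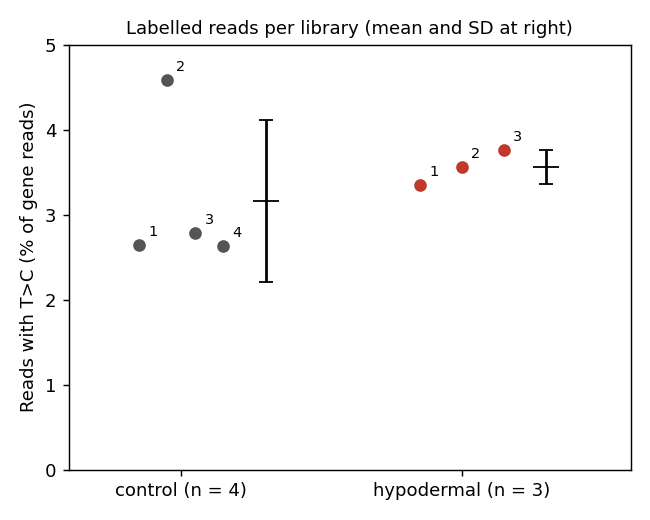
Reads with T>C as a percentage of gene reads (y axis, from 0) in each library, numbered by replicate, with the group mean and SD at the right of each group. Control replicate 2 sits at 4.58%, above the 3 hypodermal libraries at 3.35% to 3.76%, and the other 3 controls sit at 2.63% to 2.79%.

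The tissue meant to be labelled was compared next through genes known to act in it. Cuticle collagens, secreted by the hypodermis, carried 2.24% ± 0.443 labelled reads in controls (n = 4) and 2.30% ± 0.0574 in hypodermal libraries (n = 3), an exact one-sided p of 0.4. Of 113 collagen genes tested, 0 passed edgeR's test in either direction, 66 had odds ratios above 1 and 47 below, and their median log2 odds ratio was 0.09. The most-read members were ram-2 (2.35% ± 0.271 against 2.46% ± 0.328), col-71 (1.94% ± 0.398 against 2.04% ± 0.148) and col-138 (1.99% ± 0.264 against 1.93% ± 0.00732). Other hypodermal genes carried 2.43% ± 0.743 and 2.66% ± 0.0363 (exact one-sided p = 0.371), and 0 of 66 tested passed, with 4 higher and 0 lower at unadjusted p under 0.05. Among them the cuticlin gene cut-2 had 2.59% ± 0.514 and 2.16% ± 0.104, the secreted factor osm-11 1.38% ± 0.0765 and 1.63% ± 0.537, and the intermediate filament gene ifb-1 1.66% ± 1.07 and 2.69% ± 0.113. The collagen dpy-7 had 1.23% ± 1.89 and 1.35% ± 0.622, and lin-26, which encodes an epidermal transcription factor, 1.83% ± 3.45 and 0.745% ± 0.856. Seam cell genes, from the stem-like epidermal cells, carried 2.97% ± 2.74 and 3.13% ± 0.918 (exact one-sided p = 0.486), and 0 of 6 tested passed, with scm-1, wrt-2 and grd-3 the most read. Adjusted over the list alone, 0 genes of these 3 lists passed. Without control replicate 2 the control values were 2.03% ± 0.173 for collagens, 2.07% ± 0.181 for other hypodermal genes and 1.62% ± 0.668 for seam genes, with exact one-sided p of 0.05, 0.05 and 0.1. Within the flow cell batch the hypodermal libraries exceeded controls by 0.0577 points for collagens, 0.172 for other hypodermal genes and 0.00627 for seam genes, and in the other batch by 0.130, 0.412 and 1.13 points.

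Genes of other tissues were read in the same libraries. Body wall muscle genes carried 4.99% ± 0.293 labelled reads in controls (n = 4) and 5.92% ± 0.369 in hypodermal libraries (n = 3), with each hypodermal library above each control (exact one-sided p = 0.0286, 0.229 after Benjamini-Hochberg adjustment of the exact test over 16 lists). Pharynx genes carried 3.39% ± 0.423 and 4.23% ± 0.0586, also with each hypodermal library above each control (exact one-sided p = 0.0286, adjusted 0.229). Relative to all reads of each library, the log2 odds of muscle and pharynx genes differed between groups by 0.04 and 0.12 (two-sided exact permutation p = 0.971 and 0.571). Intestinal genes carried 3.71% ± 1.09 and 4.62% ± 0.414 (exact one-sided p = 0.114). Neuronal genes carried 4.22% ± 1.79 and 4.49% ± 0.609 (exact one-sided p = 0.429). Germline genes carried 2.30% ± 1.27 and 2.42% ± 0.0693 (exact one-sided p = 0.457), and sperm genes 2.57% ± 1.09 and 2.44% ± 0.233 (exact one-sided p = 0.457). Coelomocyte, excretory and gonad sheath genes carried 1.56% ± 1.70 and 1.93% ± 0.269, and glial genes 4.28% ± 4.72 and 6.90% ± 1.04 (exact one-sided p = 0.429 and 0.257). In the flow cell batch the hypodermal libraries exceeded controls by 0.717 points for muscle, 0.690 for pharynx, 1.05 for intestine and 0.394 for neurons, with germline and sperm at −0.143 and −0.256. In the other batch these 6 differences were 1.38, 1.26, 0.738, 0.222, 0.921 and 0.259 points. Without control replicate 2, 12 of the 16 lists reached the smallest possible exact one-sided p of 0.05.

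**Figure D2:**
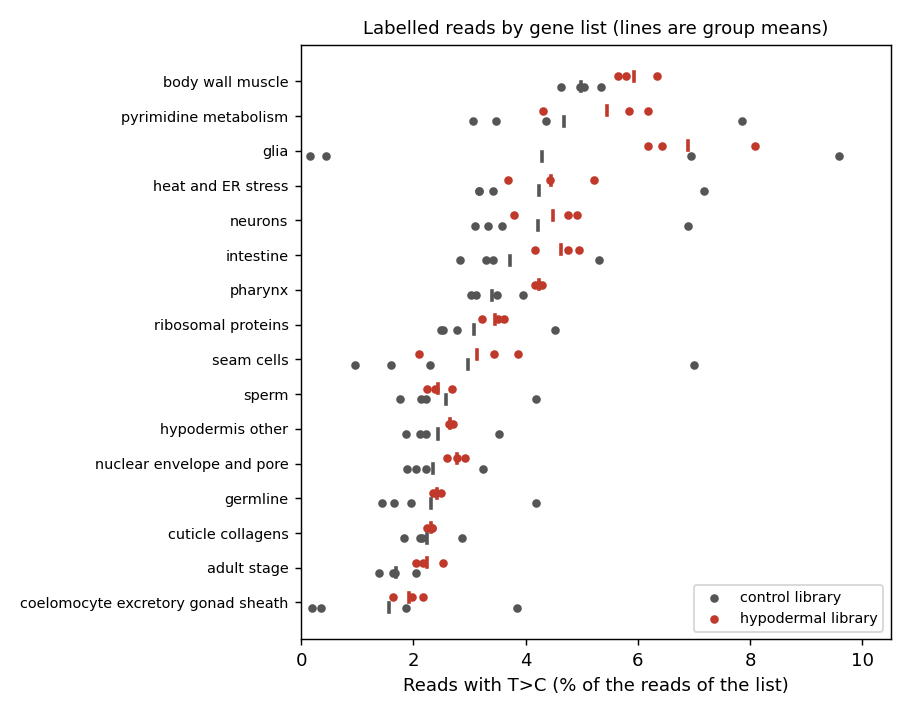
Reads with T>C as a percentage of all reads of each gene list (x axis), 1 point per library and a vertical line at each group mean, with controls (n = 4) in grey and hypodermal libraries (n = 3) in red. The collagen and other hypodermal lists lie near 2.2% to 2.7% in both groups, and body wall muscle is the highest list in controls at 4.99% and reaches 5.92% in hypodermal libraries.

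At the level of single genes of these tissues, 0 of the members named here passed edgeR's test of the labelled fraction. The muscle genes act-4 (actin), unc-54 (myosin heavy chain) and unc-15 (paramyosin) had log2 odds ratios of 0.07 (SE 0.19), 0.20 (SE 0.22) and 0.08 (SE 0.25), and unc-54 carried 6.10% ± 0.361 labelled reads in controls and 6.94% ± 0.425 in hypodermal libraries. Of 45 muscle genes 40 lay above 0, and 2 were higher and 0 lower at unadjusted p under 0.05. The intestinal aspartic proteases asp-1, asp-3 and asp-5 had 0.33 (SE 0.19), 0.49 (SE 0.30) and 0.21 (SE 0.30), while elt-2, the gut GATA factor, had 0.0681% ± 0.136 labelled reads in controls and 2.55% ± 2.27 in hypodermal libraries. The pharyngeal genes lys-8, abu-14, myo-1 and myo-2 had log2 odds ratios of 0.47, 0.29, 0.46 and 0.52, and 1 of 27 tested members was higher at unadjusted p under 0.05. Of 78 tested genes of the neuron list 0 had an unadjusted p under 0.05. Its most-read members egl-21, egl-3 and nlp-40, which act in neuropeptide signalling, had 0.04, 0.29 and 0.76, with rab-3 at 1.398 (SE 1.43). In the germline list cbd-1, car-1, glh-1 and pgl-1 had 0.76, −0.31, 0.20 and −0.71, and in the sperm list ssq-4, msp-59 and nspd-2 had 0.17, 0.25 and 0.32. For exc-9, inx-8 and clh-3 of the excretory and sheath list the values were 0.52, 1.14 and 3.26 (SE 1.68), and for the glial genes itx-1, ptr-10 and fig-1 they were 2.02, 3.49 and −0.02. Adjusted over the list alone, 1 intestinal gene passed, the saposin-like gene spp-8 (adjusted p = 0.0452 by edgeR), and 1 germline gene, glh-2 (adjusted p = 0.0391 by edgeR), and 0 genes passed in any other list.

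The second question was which single genes were labelled more in the hypodermal libraries than in the controls. Over 9821 genes, edgeR's quasi-likelihood test called 0 genes higher and 0 lower at an adjusted p under 0.05, with 281 higher and 40 lower at unadjusted p under 0.05. The median log2 odds ratio was 0.54 and 6871 genes (69.96%) lay above 0. This median was 0.85 without control replicate 2 and 0.33 without control replicate 3. The 281 higher genes became 185 without control replicate 1, 176, 181 and 136 without hypodermal replicates 1 to 3 in turn, and 94 among the flow cell libraries alone. Counts from the other tools were 0 by a quasi-binomial model (1370 higher and 412 lower at unadjusted p under 0.05), 0 by limma on log2 odds (306 and 84), and 22 higher and 1 lower (tim-1) by a beta-binomial test (1258 and 169). The smallest p belonged to mlc-4, a regulatory light chain of non-muscle myosin (WBGene00003372, WBcel235 chromosome III, 3′ UTR 3392514 to 3392690), with 0.547% ± 0.511 labelled reads in controls and 2.87% ± 0.937 in hypodermal libraries (log2 odds ratio 2.83, SE 0.65, edgeR adjusted p = 0.146). The germline helicase gene glh-2 (WBGene00001599, chromosome I, 3′ UTR 6517308 to 6517507) had 0.748% ± 0.920 and 3.62% ± 0.739 (log2 odds ratio 2.92, SE 0.85, edgeR adjusted p = 1). Values for spp-8 (chromosome IV, 3′ UTR 8483535 to 8483710) were 0.284% ± 0.286 and 3.37% ± 1.87, and for the ribosomal protein gene rpl-7A 1.67% ± 0.279 and 4.66% ± 5.12. These 4 genes were chosen after their values were seen.

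Without control replicate 2 edgeR called 20 genes higher and 0 lower, with 678 and 30 at unadjusted p under 0.05. The 20 included the translation factor gene eef-1A.1, with 1.95% ± 0.0693 labelled reads in the 3 remaining controls, 3.10% ± 0.349 in the hypodermal libraries and 4.81% in control replicate 2 (edgeR adjusted p = 2.87e-05). They also included the ribosomal protein genes rps-23, rps-3 and rpl-41.2, and asp-1, mlc-4, glh-2 and hsp-1, with log2 odds ratios of 0.52, 0.43, 0.39, 0.58, 3.04, 3.62 and 0.72. Of these values only those of mlc-4 and glh-2 lay above the median of all genes in this fit, 0.85. In the others control replicate 2 lay above the hypodermal mean. Further ribosomal protein genes among the 20 were rpl-1, rpl-7A, rpl-12, rpl-35, rps-0, rps-6, rps-14, rps-25 and rps-27. Without control replicate 4 edgeR called 1 gene higher, mlc-4, and without control replicates 2 and 3 together it called 39 higher and 1 lower. When library log odds were centred on the median gene, the split at unadjusted p under 0.05 became 81 higher and 192 lower and the median log2 odds ratio −0.22. Centred on the pooled odds of all reads, the split was 205 higher and 68 lower and the median 0.30, and 43.4% and 61.2% of genes lay above 0 under these centrings. Labelled read counts varied widely between replicates (common dispersion 0.500 in edgeR). On simulated data edgeR recovered 0% of genes with 2-fold, 8.33% with 4-fold and 13.3% with 8-fold changes in labelling.

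The other lists, of ribosomal, stress, pyrimidine, nuclear envelope and adult-stage genes, were compared in the same way. Ribosomal protein genes carried 3.08% ± 0.972 labelled reads in controls and 3.45% ± 0.202 in hypodermal libraries (exact one-sided p = 0.314), and 73 of 80 had odds ratios above 1, with 0 past the test and 4 higher and 0 lower at unadjusted p under 0.05. Limma's camera ranked them above other genes (adjusted p = 0.000505), although their median log2 odds ratio of 0.23 lay under the 0.54 of all genes. The adjusted p = 0.968 with an estimated correlation, in a test that also took log2 odds in place of the signed root of F. Limma on log2 odds at the preset correlation lost the call too (camera adjusted p = 0.768). The loss can therefore not be credited to the correlation alone. With libraries centred on the median gene the list median turned to −0.59 (camera adjusted p = 1.99e-10). The call was also lost without control replicate 1 (camera adjusted p = 0.0684), control replicate 4 (0.335) or hypodermal replicate 2 (0.105), with converted Ts in place of reads (0.109) and in the beta-binomial test (0.0538). The list median in these fits was 0.16, 0.15, 0.23, 0.20 and 0.22 in turn. The most-read members rpl-41.2, rps-23 and rps-3 had log2 odds ratios of 0.26, 0.28 and 0.28 (SE 0.17 each). Heat and ER stress genes carried 4.23% ± 1.97 and 4.45% ± 0.768, with the chaperone gene hsp-1 at 7.0% ± 6.44 and 6.29% ± 2.57, crt-1 at 3.40% ± 2.22 and 3.59% ± 0.693, and pdi-2 at 2.82% ± 0.349 and 3.47% ± 0.321. Pyrimidine metabolism genes, whose products handle uracil and its nucleotides, carried 4.69% ± 2.18 and 5.44% ± 0.992, and ndk-1, pyr-1 and ent-1 had log2 odds ratios of 0.27, −0.01 and 0.72. Nuclear envelope and pore genes carried 2.35% ± 0.613 and 2.77% ± 0.164, and ran-1, npp-9 and ima-3 had 0.36, 0.42 and 0.25. Adult-stage genes carried 1.69% ± 0.274 and 2.25% ± 0.256 (exact one-sided p = 0.0571, adjusted 0.305), with vit-6 at 0.61 (SE 0.34), col-63 at 0.55 and col-19 at −0.05. By limma's camera the adjusted p of the other 15 lists lay between 0.214 and 0.995, but 3 of them crossed 0.05 with a single control left out. Without control replicate 2 the muscle and intestine lists ranked higher (camera adjusted p = 0.0424 for both), and without control replicate 4 the collagens ranked lower (0.0388). These calls were made at the preset correlation, and over all libraries the adjusted p = 0.968 with an estimated correlation for each of these 3 lists. That test also differed in its statistic, so the effect of the correlation alone was not measured.

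The authors' deposited table lists 198 genes with a higher conversion rate in the hypodermal strain, at the authors' adjusted p from 0.0148 to 0.1. Of these 198 genes in the authors' deposited table, 197 had odds ratios above 1 here, 64 had an unadjusted p under 0.05 and 0 passed edgeR's adjusted threshold. The beta-binomial test called 23 genes, of which 19 are in the authors' deposited table, and of the 20 genes edgeR called without control replicate 2, 3 are. In the authors' deposited table kin-3, a casein kinase subunit, had mean conversion rates of 0.0688% in controls and 0.155% in hypodermal libraries, a ratio of 2.25, and the collagen gene dpy-3 had 0.0160% and 0.343%, a ratio of 21.4. Members were counted within a background of 7584 genes set here, since the genes tested by the authors are not given. The authors' p-values and adjusted p-values point to a smaller set. In this background the authors' deposited table holds 2 of 103 collagens (col-174 and dpy-3), 1 of 60 other hypodermal genes (cnc-2) and 5 of 43 body wall muscle genes (lev-11, pat-10, tnt-2, unc-22 and unc-54). Chance placement, with no allowance for read depth, gives 2.69, 1.57 and 1.12. For muscle the two-sided Fisher's exact test gave p = 0.00496, or 0.0793 after adjustment over 16 lists. The authors' deposited table also holds 4 ribosomal protein genes (rla-0, rpl-7, rps-2 and rps-23), 2 nuclear pore and transport genes (npp-13 and xpo-1), spp-8 and glh-2, and 0 of the neuronal, pharyngeal, sperm, seam, glial, excretory, adult-stage, stress and pyrimidine lists. The authors' deposited table was made from these same libraries, so it is not independent evidence of direction.

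The third comparison asked how alike the animals of the strains were in total reads per gene. The antimicrobial peptide gene nlp-27 (WBGene00003765, WBcel235 chromosome V, 3′ UTR 3989714 to 3989770) fell by 3.04 on the log2 scale (SE 0.38), from 99.1 ± 38.6 CPM (read counts scaled to library depth) in controls (n = 4) to 12 ± 1.23 in hypodermal libraries (n = 3). The P-glycoprotein gene pgp-6 (WBGene00004000, chromosome X, 3′ UTR 10871181 to 10871345) had 915 reads over the control libraries and 1 over the hypodermal libraries, or 7.63 ± 3.99 against 0.00491 ± 0.00851 CPM. Its pooled ratio of control to hypodermal reads, scaled by depth, was 1082 with a 95% counting interval of 194 to 42777. Both passed edgeR's test (adjusted p = 0.0358 for each), and of 12465 genes tested 0 were higher and 2 lower, with 91 higher and 193 lower at unadjusted p under 0.05. DESeq2 called 9 higher and 15 lower, with 100 and 295 at unadjusted p under 0.05. Without control replicate 1, 3 or 4 or hypodermal replicate 1, 2 or 3, edgeR called 0 genes lower, and without control replicate 2 it called 1, pgp-6 (edgeR adjusted p = 0.0334). For nlp-27 the edgeR adjusted p without control replicates 1 to 4 in turn was 0.0507, 0.0714, 0.0589 and 0.120, and without hypodermal replicates 1 to 3 it was 0.732, 0.486 and 0.430, while its log2 fold change stayed between −3.21 and −2.80. For pgp-6 it was 0.107, 0.0589 and 0.287 without control replicates 1, 3 and 4 and 0.732, 0.486 and 0.430 without the hypodermal replicates. With a batch term the adjusted p was 0.0595 for both genes, and among the flow cell libraries alone it was 0.272 for nlp-27 and 0.470 for pgp-6 by edgeR. The log2 fold change of nlp-27 was then −2.98 and −3.11. For pgp-6, whose fitted fold depends on the prior count, it was −9.58 and −9.51, against −9.22 over all libraries and −10.38 to −8.87 with single libraries left out.

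Several genes outside the rule for named genes stood next in line and were chosen after their values were seen. The germline helicase gene glh-2 had 45.6 ± 17.0 CPM in controls and 208 ± 36.2 in hypodermal libraries (log2 fold change 2.19, SE 0.35), with an edgeR adjusted p of 0.183 over all genes and 0.00410 adjusted over the list alone. Its paralog glh-1 (chromosome I, 3′ UTR 6857394 to 6857529) had 464 ± 78.1 and 435 ± 60.4, and reads of near-identical stretches could not be told apart from the counts. The oocyte RNA-binding protein gene puf-5 had 187 ± 27 and 81.5 ± 16.5 (log2 fold change −1.20, SE 0.28, edgeR adjusted p = 0.0443 adjusted over the list alone). The caenacin gene cnc-4, another antimicrobial peptide, had 155 ± 24.5 and 360 ± 82.8, and the hedgehog-related gene grd-2 5.86 ± 0.740 and 18.9 ± 3.24. The collagen gene col-137 had 166 ± 65.9 and 42.5 ± 12.1. Adjusted over the list alone, cnc-4, grd-2 and col-137 had edgeR adjusted p of 0.0324, 0.0102 and 0.0447, and each was 0.658 or more over all genes.

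**Figure D3:**
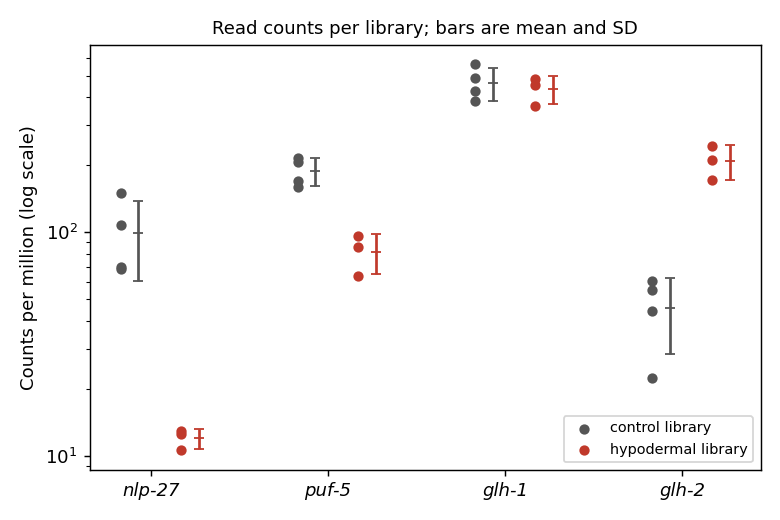
CPM (y axis, log scale) of nlp-27, puf-5, glh-1 and glh-2 in each control (grey, n = 4) and hypodermal (red, n = 3) library, with bars at the mean and SD. The hypodermal libraries lie below the controls for nlp-27 (12 against 99.1) and puf-5 (81.5 against 187), above them for glh-2 (208 against 45.6) and among them for glh-1 (435 against 464).

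Germline genes as a list fell in the hypodermal libraries at the preset correlation, with 61 of 70 below 0 and a median log2 fold change of −0.33 (limma camera adjusted p = 2.42e-08). The adjusted p = 0.231 with an estimated correlation. Their summed CPM were 8435 ± 1312 in controls (n = 4) and 6870 ± 440 in hypodermal libraries (n = 3), with each hypodermal library below each control. Singly, 0 of the 70 passed over all genes and 1 was higher and 7 lower at unadjusted p under 0.05, and adjusted over the list alone 1 was higher (glh-2) and 1 lower (puf-5). The eggshell gene cbd-1 had a log2 fold change of −0.18, car-1 −0.84, the P granule gene pgl-1 −0.72 (SE 0.33) and glh-1 −0.09. Among the flow cell libraries alone the list median was −0.28 (limma camera adjusted p = 2.95e-05).

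Adult-stage genes had a list median of −0.73 with 8 of 10 below 0 (limma camera adjusted p = 0.00686), and summed to 3301 ± 1114 CPM in controls and 2261 ± 390 in hypodermal libraries. The adjusted p = 0.554 with an estimated correlation, 0.0818 without control replicate 2, 0.0789 without hypodermal replicate 3, 0.321 without control replicates 2 and 3 and 0.0646 among the flow cell libraries alone. The list median was −0.50 without control replicate 2, −0.66 without hypodermal replicate 3 and −0.80 among the flow cell libraries, but −0.18 without control replicates 2 and 3. The yolk protein gene vit-6 had 1231 ± 454 and 688 ± 166 CPM, and the adult collagen genes col-19 and col-63 had log2 fold changes of −0.69 and 0.55. Sperm genes had a list median of −0.17 with 44 of 58 below 0 (limma camera adjusted p = 0.0230), 0 past the test singly and 0 at unadjusted p under 0.05. The adjusted p = 0.902 with an estimated correlation, 0.0679 among the flow cell libraries, and 0.132 and 0.191 without hypodermal replicates 1 and 3. Without control replicate 2, which held 9496 CPM of sperm genes against 4331 to 5143 in the other controls, the list median was 0.16 (camera adjusted p = 0.663). The sperm genes ssq-4, msp-59 and nspd-2 had log2 fold changes of −0.69, −0.21 and −0.41.

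The remaining lists did not pass limma's camera in read counts with TMM scaling, but 3 lay close to the threshold and crossed it in other settings. Cuticle collagens summed to 76504 ± 8688 CPM in controls and 73486 ± 8344 in hypodermal libraries (median log2 fold change −0.01, adjusted p = 0.517 by camera), and 0 of 121 passed singly, with 4 higher and 12 lower at unadjusted p under 0.05. Other hypodermal genes had a median of 0.26 with 47 of 70 above 0 (camera adjusted p = 0.0529, but 0.0445, 0.0202 and 0.0358 without control replicate 3, control replicate 4 and hypodermal replicate 2), and nlp-27 alone passed. Seam cell genes had a median of 0.23 (camera adjusted p = 0.0529). Without control replicate 4 their median was 0.46 (camera adjusted p = 0.0108), and without hypodermal replicate 1 it was 0.42 (0.00269). Ribosomal protein genes had a median of −0.10 (camera adjusted p = 0.0529), and took 386067 CPM in control replicate 2 against 181173 to 216980 in the other controls. Without control replicate 1, 3 or 4 or hypodermal replicate 2 the ribosomal list passed as lower (camera adjusted p = 0.000588, 0.0308, 0.0112 and 0.00495), and without control replicate 2 it passed as higher, with a median of 0.24 (0.0355). With DESeq2's size factors the other hypodermal and seam lists passed as higher and the ribosomal list as lower (camera adjusted p = 0.0461 for each), and on DESeq2's test statistics the values were 0.0239, 0.0224 and 0.0137. With a batch term the other hypodermal and seam lists passed (camera adjusted p = 0.0325 for each), without a read filter the seam and ribosomal lists (0.0161 and 0.0483), and at a mean of 100 reads the other hypodermal list (0.0165). For the other hypodermal, seam and ribosomal lists the adjusted p = 0.554, 0.812 and 0.902 with an estimated correlation. Without hypodermal replicate 2 camera also called the collagens lower (adjusted p = 0.0162) and the glia higher (0.0189), for which over all libraries the adjusted p = 0.902 and 0.554 with an estimated correlation. Body wall muscle, pharynx, neuron and intestine genes had medians of 0.11, −0.09, 0.01 and −0.03 (camera adjusted p = 0.652, 0.680, 0.954 and 0.372). Glial genes had a median of 0.47 and excretory and sheath genes 0.17 (0.193 and 0.954). Heat and ER stress, pyrimidine and nuclear envelope genes had 0.03, −0.10 and −0.01 (camera adjusted p = 0.954, 0.379 and 0.954). Of the muscle genes, unc-54 had 3633 ± 3658 CPM in controls, where control replicate 3 held 9050, and 2944 ± 53.1 in hypodermal libraries.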

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

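The tests of control replicate 2, of the germline tissue behind glh-2, and of a single library or the batch behind the germline list were chosen only after the result was seen, while those of the other splits, of glh-1, of the construct and of animal age were set down before their result.

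Among the 4 control libraries, 24 of 150 tested values stood far from the other 3 by Dixon's ratio, where chance gives about 1 in 20, or 7.5, for independent normal values. The 150 values overlap, since lists share reads with their members and with all genes. Where the other controls held 0%, as for elt-2 and fig-1, any non-zero library was flagged. The excess over 7.5 is therefore only a rough guide. Control replicate 2 accounted for 16 of the 24, control replicate 4 for 4, and control replicates 1 and 3 for 2 each. In read counts control replicate 3 had the lowest mean correlation with the other libraries (0.818, against 0.857 for control replicate 2). Control replicate 2 stood high in labelled reads of all genes (4.58% against 2.63% to 2.79%) and in converted Ts (0.231% against 0.106% to 0.121%). It stood high in the labelled percent of neurons (6.90% against 3.10% to 3.57%), ribosomal protein genes (4.52% against 2.48% to 2.78%) and stress genes (7.18% against 3.17% to 3.41%). The same held for the labelled percent of car-1 (9.77%), glh-1 (3.65%), rps-23 (3.82%), rps-3 (2.66%), hsp-1 (16.5%), ima-3 (10.2%), dpy-7 (4.04%) and pgp-6 (11.1%, from 1 of 9 reads). In CPM it stood high for sperm genes (9496 against 4331 to 5143) and asp-3 (2033 against 1201 to 1258) and low for inx-8 (23.8 against 27.9 to 28.7).

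Control replicate 4 stood high in CPM of seam cell genes (322 against 164 to 189), scm-1 (179 against 90.5 to 101) and dpy-7 (59.9 against 23.02 to 23.47), and in the labelled percent of fig-1 (7.43% against 0%). Control replicate 3 held 9050 CPM of unc-54, where the others held 1014 to 2342, and 0.663% labelled reads of nspd-2 against 2.12% to 2.39%. Control replicate 1 held 7.003% labelled reads of lin-26 against 0% to 0.334%, and 0.272% of elt-2 against 0%.

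The raised T>C share of control replicate 2 was weighed against technical explanations. Over 10 genes that part the strains without this library, its median place from hypodermal (0) to the other controls (1) was 0.982, which argues against a swapped label. A background added alike to every read is argued against, as the whole of the rise, by converted Ts. These rose by 0.173 points in neurons and 0.0580 in body wall muscle. The gap of 0.115 points compares with an SD of 0.0262 among the other controls. The rise was near the muscle value in collagens (0.0581), other hypodermal (0.0551), intestinal (0.0607), pharyngeal (0.0524), nuclear envelope (0.0615) and excretory genes (0.0633). It was larger in germline (0.111), ribosomal (0.116), sperm (0.141), stress (0.186), pyrimidine (0.246), seam (0.276) and glial genes (0.331). Adult-stage genes rose by 0.0238. A smaller part common to all lists stays open. Longer coverage of Ts is argued against by 18.0 covered Ts per read, under the 20.6 to 22.4 of the other controls. The share of its mapped reads, back-calculated from the deposited CPM, that were counted in genes was 40.02% against 55.9% to 76.5% elsewhere. No biological explanation was tested, and a difference in RNA or library handling may remain.

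The gene glh-2 had more reads and more labelled reads in the hypodermal libraries. More germline tissue is argued against by the other 69 germline genes, which did not rise and had a median log2 fold change of −0.34. Its bootstrap SE of 0.05 was taken over genes, which may vary together, and does not measure the spread between libraries. In summed CPM of the list, with glh-2 included, each hypodermal library lay below each control. Reads moved from the paralog glh-1 stay open, since glh-1 changed by −29.6 CPM with an SE of 52.3, against a gain of 162 in glh-2. A candidate explanation is a transcript of the hypodermal construct that ends in the glh-2 3′ UTR: the added reads were 4.59% labelled on average (SD 1.17; 4.52%, 5.80% and 3.46% in hypodermal replicates 1 to 3), at or above all reads in 2 of 3 libraries. This percent largely follows from the reads and labelled percent for which glh-2 was chosen, so it is no separate support for a construct transcript. The spread also keeps this open, and the sequence of the construct was not used here.

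The germline list was lower in read counts of the hypodermal libraries by camera at its preset correlation, a call lost with an estimated correlation (adjusted p = 0.231). The list median stayed between −0.38 and −0.28 with any library left out and was −0.32 with a batch term. These medians argue against a single library or the flow cell batch as the source of the lower median. At the preset correlation the largest camera adjusted p was 0.000151 with a library left out, and 5.09e-08 with a batch term. These p-values cannot decide the matter, since the list also passed in other splits of the libraries. Slightly younger animals could lower oocyte genes more than meiotic ones: 20 oocyte genes differed from 16 meiotic genes by −0.22 on the log2 scale, but with an exact one-sided p of 0.171, so age and strain cannot be told apart. Of the 35 splits of the libraries the real one gave the smallest adjusted p of this list (2.42e-08, next 2.81e-07). This rank, 1 of 35, is the most extreme that the splits allow, without adjustment for the 8 results put through them. The list also passed in 14 of the 34 other splits, so chance is not excluded. The strain itself stays open as an untested biological difference.

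Other splits of the 7 libraries into 4 and 3 gave results as large in several cases, so chance cannot be excluded for these. The 281 higher genes at unadjusted p under 0.05 were reached or passed in 5 of 35 splits, with 604 the highest other, and the median log2 odds ratio of 0.54 in 5, with 0.81 the highest other. For genes with changed reads, 2 of 35 splits, the real one included, gave 2 genes, the highest count of any. The ribosomal list in labelling had as small an adjusted p in 14 splits (0.000505 against 3.85e-28), the adult-stage list in reads in 4 (0.00686 against 5.44e-06) and the sperm list in reads in 21 (0.0230 against 6.63e-12).

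For genes past the adjusted threshold in labelling the splits decide nothing, since the real count was 0 and all 35 splits give at least that. The highest other count was 40, when control replicate 2 was put with the 3 hypodermal libraries against the other 3 controls. It points to a structure of the samples in which control replicate 2 lies apart from the other controls, and that split still holds the contrast of the strains, which without control replicate 2 gave 20 genes.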

How the results depend on the processing

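The beta-binomial test, limma on log2 odds, the batch term, the flow cell libraries alone, pooled centring, leaving out control replicates 2 and 3 together and odds relative to all reads were added after seeing the data, and for the changes given here the cause was not tested unless named. The count of 0 genes in labelling by edgeR held with converted Ts, the quasi-binomial model, limma, both centrings, other filters, the batch term, the flow cell libraries and a threshold of 0.1. Each entry tested alone also gave 0 of 19425 (621 higher and 95 lower at unadjusted p under 0.05). The beta-binomial test gave 22 higher and 1 lower, 19 of them in the authors' deposited table, and leaving out control replicates 2 and 3 gave 39 higher and 1 lower, 3 of them in that table. With single libraries left out the higher count ran from 0 to 20 and the overlap with the table from 0 to 3. For reads, DESeq2 gave 9 higher and 15 lower, no read filter gave 1 higher, and the batch term and the flow cell libraries gave 0 lower. With single libraries left out the lower count ran from 0 to 1, with fewer samples in each fit.

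The ribosomal list in labelling turned with median centring (−0.59), pooled centring (median 0.0116, camera direction down), limma on log2 odds (median 0.23, camera direction down) and odds relative to all reads (−0.00273). The sperm list in reads turned to 0.16 without control replicate 2, to 0.16 without control replicates 2 and 3, and ran from −0.28 to 0.16 with single libraries left out. Over all alternatives, log2 odds ratios of named genes kept their sign and their side of the threshold in 1120 results, whatever the size of the shift. They changed sign while uncalled in 106 and gained a call in 6. For lists in labelling, by the direction of the list's test, these numbers were 271, 59 and 11, and 7 lost the call. Lists in reads kept in 185, changed direction uncalled in 32, gained in 27 and lost in 10. Fold changes of named genes kept in 799, changed sign uncalled in 78 and lost the call in 19, all of them nlp-27 or pgp-6. Some kept results repeat the main fit and could not change. Among the 1120 these are 56 at a threshold of 0.1 and 56 with an estimated correlation, and among the 799 they are 56 with an estimated correlation. The muscle list in labelling gained a call in the quasi-binomial model (camera adjusted p = 9.59e-05) and the beta-binomial test (0.0481), and as lower the collagens with median centring (1.64e-08) and pooled centring (6.19e-05) and the sperm list with median centring (0.0107). The intestine list gained one among the flow cell libraries (0.0422) and the germline list without control replicates 2 and 3 (0.0211). All these are at the preset correlation, and over all libraries each of these lists had an adjusted p = 0.968 with an estimated correlation. For labelling that test also used log2 odds in place of the signed root of F. On simulated data the quasi-binomial and beta-binomial models gave 11.8% of unchanged genes an unadjusted p under 0.05.

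With the replicate number as a block edgeR gave 0 genes in labelling (185 higher and 12 lower at unadjusted p under 0.05) and 0 in reads (219 and 209), and the library difference was 0.224 points. The ribosomal list in labelling lost its call with the block (camera adjusted p = 0.177) and the collagens gained one as lower (median −0.02, 0.0375), and in reads the other hypodermal, seam and ribosomal lists gained one (0.0216, 0.0293 and 0.0125). The numbers were not shown to pair the samples: same-numbered libraries deviated together across genes with correlations of 0.00728, −0.00688 and −0.0140 in log2 odds and 0.364, 0.0954 and −0.0772 in log2 CPM, and not every library correlated best with its own number. The 0.364, the highest of all pairs in log2 CPM, was of control replicate 1 and hypodermal replicate 1. Their headers both name no flow cell, so pairing and batch cannot be told apart there. The median tested gene had 80 reads in control replicate 2 and 164 in control replicate 3, against 379 to 1453 in the other libraries, and depth was not weighed against the spread between replicates.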

Other observations

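The tests of muscle against collagens and of neighbouring genes below were chosen only after the result was seen.

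Body wall muscle genes were converted more than cuticle collagens and other hypodermal genes in both strains. In the controls, which lacked FLP, converted Ts made up 0.207% ± 0.0312 of covered Ts in muscle genes, 0.151% ± 0.0330 in pharynx genes and 0.135% ± 0.0311 in intestinal genes. Other lists lay above or between these in the control mean, with a wider spread: pyrimidine metabolism genes at 0.210% ± 0.127, glial genes at 0.187% ± 0.212, sperm genes at 0.174% ± 0.0723, ribosomal protein genes at 0.172% ± 0.0594, neuronal genes at 0.169% ± 0.0871, stress genes at 0.162% ± 0.0933 and seam cell genes at 0.136% ± 0.140. Converted Ts made up 0.104% ± 0.0297 in cuticle collagens, 0.0901% ± 0.0276 in other hypodermal genes and 0.0933% ± 0.0568 in germline genes (SD, n = 4). Muscle lay above collagens, other hypodermal genes and germline genes in each of the 7 libraries (two-sided exact sign test, p = 0.0156 over both strains and 0.125 over the 4 controls alone, the smallest that 4 libraries allow). In control replicate 2 muscle, at 0.251%, lay below glial (0.435%), pyrimidine metabolism (0.395%), seam cell (0.343%), stress (0.302%), neuronal (0.299%), sperm (0.279%) and ribosomal protein genes (0.259%). Seam cell genes averaged 0.0673% ± 0.0283 in the other 3 controls. The muscle value was 2.04 ± 0.236 times the collagen value in controls and 2.34 ± 0.167 times in hypodermal libraries. The excretory and gonad sheath list had the lowest control value at 0.0394% ± 0.0400, and its highest library was control replicate 2.

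The near-total loss of pgp-6 reads stood apart from the counts of 3 nearby genes on chromosome X that had enough reads to compare. Reads of pgp-6 numbered 667, 9, 71 and 168 in control replicates 1 to 4 and 1, 0 and 0 in hypodermal replicates 1 to 3. The gene pgp-5, at 10854320 to 10854380, had 292, 29, 0 and 91 reads in controls and 129, 10 and 34 in hypodermal libraries, or 3.98 ± 2.71 against 1.46 ± 0.847 CPM. Its mean was lower, but with a log2 fold change of −1.53 (SE 1.19) a fall was neither shown nor excluded (edgeR adjusted p = 1). The gene F47B10.5, at 10889041 to 10889156, had 9.09 ± 5.30 and 10.8 ± 2.84 CPM, and haly-1 (histidine ammonia lyase), at 10893567 to 10893688, had 12.56 ± 3.43 and 11.2 ± 0.535. The gene pgp-8, between pgp-5 and pgp-6 at 10859351 to 10859509, had at most 2 reads in any library, too few to compare.

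Labelled reads were spread unevenly over genes. Among genes with at least 200 and under 500 reads in a library, those with no T>C read made up 43.2%, 2.18%, 36.5% and 15.5% in control replicates 1 to 4 and 30.3%, 21.4% and 9.86% in hypodermal replicates 1 to 3. If reads were independent and equally likely to be labelled, these shares would be 0.0879% or less in each library. Control replicate 2, with the fewest reads, had the lowest share.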
